A study of Mus musculus with 5 samples.

How the data were processed

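Total RNA of mouse C3H10T1/2 cells was measured on 5 Affymetrix Mouse Gene 1.0 ST arrays, to which biotin-labelled cDNA is hybridized. Their probes are spread along each transcript. Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum, virus was added to cells that had not reached confluence, and cells were harvested 4 days after infection. Each of the 5 groups has 1 array. The groups are cells without virus, cells with a lentivirus carrying an empty vector, cells with a lentivirus carrying HA-tagged PPARg, and the M-fraction and the A-fraction of cells given both Myc-tagged MyoD and HA-tagged PPARg. Per the labels, the fractions were made by cell size, the M-fraction being enriched for myotubes and the A-fraction for adipocytes.

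Per the series design text and the submitters' processing notes, the authors imported the scanner files into GeneSpring GX 11.0.2, normalized the probe intensities and calculated 1 signal per probe set with RMA, which corrects background, normalizes over arrays and summarises probes. The deposited values are intensity values on a linear scale, from about 20.0 to 15892.4, with array medians between 87.2 and 90.7. They are not centred per gene. The step from RMA's log2 scale to a linear one, and any lower limit behind the edge near 20.0, are not given in the sources used here. The log2 of each deposited value was taken here, and every difference is a difference of log2 signals. A fold is the ratio of 2 such signals. RMA signals hold no detection call and include nonspecific signal, so a fold against a signal near the lower edge is a fold over that level and not over zero. No detection p-value was used, and the number of arrays limits the precision.

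Of the 28853 probe sets, 21789 were paired with 1 gene symbol in the platform annotation, 1621 with several, and 5443 were not listed with a gene. Of the probe sets with 1 symbol, 21698 matched the RefSeq gene table of assembly GRCm38.p6 through their Entrez number, which changed 0 symbols; the others kept the annotation's name. That table was used for names alone, and no coordinates are given because no genome build is named for the array values. Probe sets with several symbols or none were left out of the gene comparisons. This gave 19938 genes. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 5 arrays was taken. Genes were kept where the highest of the 5 signals was at or above the 30th percentile of the gene table, a signal of 57.57 (log2 5.847), which left 14847 genes. Members of near-identical families, such as the myosin heavy chains Myh1 and Myh3, the carboxylesterases Ces1d and Ces1f, and Prl2c5, can share probes, and their values are uncertain to that extent.

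The groups, the gene lists, the rules and the alternatives were fixed before the data were examined. With 1 array per group there is no test, no SD and no p-value. A gene was called where 2 arrays lay at least 2-fold apart. Pairs of arrays were compared as follows, the empty vector with the non-infected cells, PPARg alone with the empty vector, each fraction with the empty vector, the fractions with each other, and the A-fraction with PPARg alone. Genes named in the text are Pparg, Myod1, Myog, Mef2c, Cebpa, Fabp4, Adipoq, Plin1, Cd36, Acta1, Myh3 and Ckm in every array. To these come the 8 highest and 8 lowest genes of each comparison (3 and 3 for the control pair), which in comparisons with the empty vector also had to be 2-fold apart from the non-infected array in the same direction. Predicted genes without a name, olfactory and vomeronasal receptors and small RNAs were skipped. Of each gene list, up to 4 members with the largest difference, and members 2-fold against the list's direction, could be named; for lists given mainly by their median some were left out. Any other gene was chosen after its values were seen, and the text says so.

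The 34 lists cover fat cell markers, PPARg target genes, adipokines, adipogenic transcription factors, lipid synthesis, lipid droplets, fatty acid oxidation and thermogenic fat. For muscle they cover the sarcomere, myogenic regulators, myoblast fusion, the acetylcholine receptor and synapse, calcium handling, muscle energy metabolism and smooth muscle. The list called myogenic regulators also holds muscle genes that are not regulators, such as Chrna1, Des and Cdh15. The rest are fibroblast matrix, bone, cartilage, the cell cycle, the interferon response, inflammation, TGF-beta, Notch, Wnt, p53, the unfolded protein response, sterol synthesis, the respiratory chain, glycolysis, ribosomal proteins, and markers of macrophages, endothelium, neurons and epithelium. For each list the median log2 difference was set beside the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. These counts of random lists describe these arrays and are not p-values. Lists share members: 11 of the 16 measured PPARg target genes are also among the 20 fat cell markers.

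Overlaps of calls against the shared empty-vector array are given with the overlap of independent lists, with 1000 simulated sets of unchanged arrays that share a control, and with the non-infected array as the control of 1 of the arrays. The simulated arrays drew their differences from the control pair among genes of like signal. The same code was tested on simulated data before use. Over 14847 genes, in simulated arrays of PPARg against the empty vector, it called 10.0% of genes shifted by log2 0.5, 90.0% of those shifted by 1.5, all of those shifted by 2.0 or 3.0, and 4.1% of unshifted genes. The simulated noise was drawn from the control pair, of which 4.23% of genes lay 2-fold apart. The 4.1% therefore follows from that choice and is not an error rate measured on replicates. Linear shares, such as the signal of the A-fraction over the empty vector divided by that of the M-fraction over the empty vector, have 95% intervals from 10000 bootstrap draws over genes, which cover the spread over genes and not over cultures. The test of mixing was also run on 1000 simulated sets in which the A-fraction was an exact mixture and the PPARg culture differed from its part in it as the controls differ, by 0.5 of that or by 0.25 of that, which was chosen after the results were seen.

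The alternatives were quantile normalization of the gene table, equal array medians, no level filter, a filter at the 50th percentile, the mean of a gene's probe sets, a 3-fold threshold and the non-infected array as the control. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and the plots matplotlib 3.10.9.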

Results

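C3H10T1/2 cells, a mouse embryonic mesenchymal line with fibroblast form that can be turned into fat, muscle, bone or cartilage cells, were profiled on 5 arrays. PPARg is the nuclear receptor that drives fat cell differentiation, and MyoD is the transcription factor that drives skeletal muscle differentiation. The series asks how such master regulators of different fates act against each other in 1 cell population. The arrays hold non-infected cells, cells with an empty-vector lentivirus, cells with PPARg alone, and the myotube-enriched M-fraction and adipocyte-enriched A-fraction of cells given both factors. There were no replicates, so every difference below lacks a replicate check. No array of cells with MyoD alone was analysed here.

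The arrays had like overall signal, with medians of 87.2 (non-infected), 89.4 (empty vector), 90.7 (PPARg), 88.9 (M-fraction) and 89.5 (A-fraction). Across genes, which are not independent replicates, log2 signals correlated at r = 0.9592 between the 2 controls, 0.9743 between PPARg alone and the A-fraction, and 0.9571 between the fractions. The correlation was lower between PPARg alone and the M-fraction, at 0.9024. Against the empty vector it was 0.8289 for PPARg alone, 0.8545 for the A-fraction and 0.8103 for the M-fraction.

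The introduced factors were read first. Pparg had a log2 signal of 8.96 in non-infected and 9.72 in empty-vector cells, and of 12.03 with PPARg alone, 11.94 in the A-fraction and 11.70 in the M-fraction, which is 4.97, 4.66 and 3.95 times the empty vector. Myod1 was at 6.56, 6.75 and 6.64 in the arrays without MyoD virus, at 9.004 in the M-fraction and at 8.23 in the A-fraction. Both genes followed the labels. The species of the introduced sequences is not given in the sources used here, so these signals cannot be divided into introduced and endogenous transcripts.

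Markers of both lineages were high in both fractions. Adipoq, which encodes the fat cell hormone adiponectin, had log2 signals of 12.89 with PPARg alone, 12.64 in the A-fraction and 11.85 in the M-fraction, against 5.34 with the empty vector. The fatty acid binding protein gene Fabp4 was at 12.43, 12.32 and 12.07, and the fatty acid transporter gene Cd36 at 12.18, 12.28 and 12.26. The lipid droplet coat gene Plin1 (12.21, 11.84 and 10.67) and Cebpa, a transcription factor of fat cells (10.14, 10.03 and 8.70), were lower in the M-fraction. Myog, the muscle transcription factor myogenin, had 11.68 in the M-fraction and 10.18 in the A-fraction, against 5.996 with PPARg alone and 5.73 with the empty vector. Acta1, skeletal muscle actin, had 12.90, 11.24, 7.64 and 7.35 in the same order. The embryonic myosin gene Myh3 (11.19, 7.96, 5.92 and 5.21) and muscle creatine kinase Ckm (10.61, 8.53, 7.33 and 7.13) differed more between the fractions. Mef2c, a partner of the muscle regulators, had 9.11 in the M-fraction and 6.95 in the A-fraction. The A-fraction value was below the 7.48 of the empty vector, near the 6.87 of non-infected cells and above the 5.98 of PPARg alone.

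**Figure D1:**
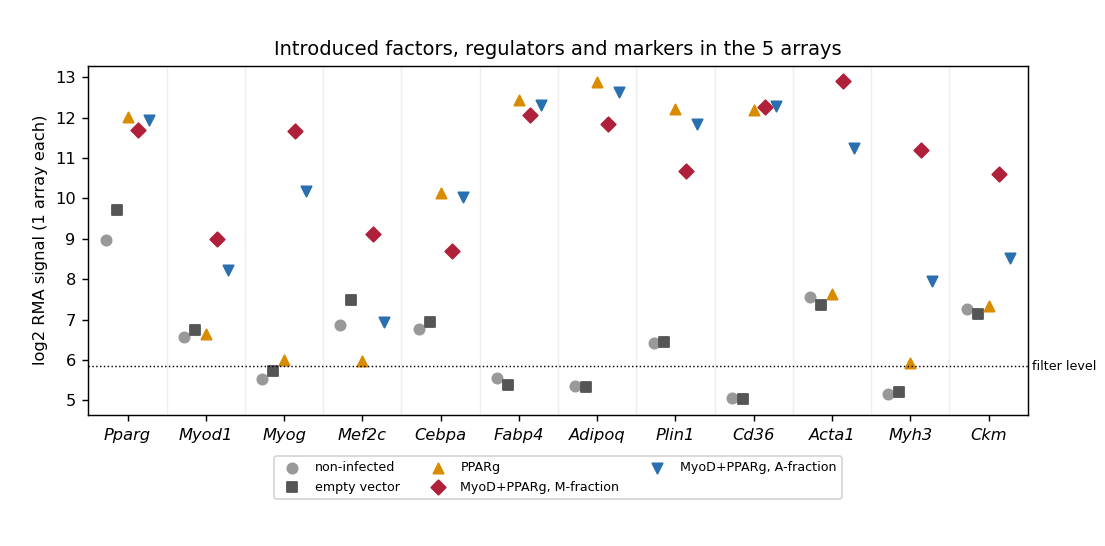
The log2 RMA signal (vertical axis) of the 12 genes fixed beforehand, with 1 point per array; the dotted line is the level filter at 5.847. Pparg was near 12 in the 3 arrays with PPARg virus, Adipoq was at 11.85 or above there, and Myog was at 11.68 in the M-fraction and 10.18 in the A-fraction against 5.996 with PPARg alone.

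The empty vector was set against non-infected cells to see how far 2 arrays without either factor lay apart. The harvest time and density of the non-infected culture are not given in the sources used here, so these differences cannot be ascribed to the virus. Pgm5, a phosphoglucomutase-like protein of cell junctions, had a log2 difference of 3.92, and Islr (3.67) and Pi15 (3.58) came next. The lowest were the branched-chain aminotransferase gene Bcat1 (log2 difference -2.85), the amino acid transporter gene Slc7a5 (-2.74) and Idi1 of sterol synthesis (-2.51). In all, 313 genes were at least 2-fold higher and 315 at least 2-fold lower, or 4.23% of 14847. The 95th percentile of the absolute difference was 1.88-fold.

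Cell cycle genes were lower with the empty vector. Of 39 measured cell cycle genes, 32 were at least 2-fold lower and 0 higher, with a median log2 difference of -1.29, and Bub1 (-1.96), Mcm5 (-1.77), Tpx2 (-1.74) and Plk1 (-1.69) differed most. Sterol synthesis genes were lower too, 12 of 17 by at least 2-fold (median -1.34), with Msmo1 at -2.05, Lss at -1.97 and Cyp51 at -1.85. For both lists, 0 of 10000 random lists had a median as low. Interferon-stimulated genes were higher, 5 of 21 by at least 2-fold (median 0.38), led by Ifit1 (8.6-fold), Ifit3 (6.3-fold), Usp18 (2.9-fold) and Oasl2 (2.4-fold). Dcn, a small matrix proteoglycan, was at log2 7.83 without virus and 11.13 with the empty virus, and Lum, a related one, differed by 2.13. Ccn2, by contrast, was lower (-2.05). The fibroblast matrix list as a whole had a median of 0.02. Wnt genes had 6 of 20 members at least 2-fold higher and 0 lower (median 0.20), among them the secreted Wnt antagonists Sfrp2 (3.02), Sfrp1 (2.93) and Dkk2 (2.26). Glycolysis had a median of -0.43 with 1 of 14 members 2-fold lower (Pgk1, -1.12), and inflammation one of 0.26 with 3 of 17 higher and 1, Ptgs2 (-1.25), lower. Fat cell markers (median -0.00) and sarcomere genes (0.03) had 0 and 1 members 2-fold apart. With these gaps between the controls, many of the lowest genes and of the lists are also given against the non-infected array below, though not all that moved.

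PPARg alone was compared with the empty vector to describe the fat cell programme. Adipoq was 187-fold, Car3, a carbonic anhydrase abundant in fat and muscle, 172-fold, Cd36 142-fold and Fabp4 132-fold higher. Next came the glycerol channel gene Aqp7 (128-fold), lipoprotein lipase Lpl (118-fold), glycerol-3-phosphate dehydrogenase Gpd1 (103.0-fold) and the droplet fusion protein gene Cidec (87.7-fold). Most of these had empty-vector signals near the lower end of the arrays, so these folds depend on that level. The lowest genes were Sfrp2 (-5.95), Ccn3 (-5.09), the complement protease C1s1 (-4.73), Igsf10 (-4.63), the collagen hydroxylase P4ha3 (-4.61), the myosin light chain Myl9 (-4.53), the endocytic adaptor Dab2 (-4.50) and the growth factor Fgf7 (-4.46). Against non-infected cells Sfrp2 was at -2.94, Ccn3 at -2.80, C1s1 at -1.65 and Dab2 at -3.35, while P4ha3 stayed at -4.67 and Fgf7 at -4.42. In all, 1110 genes were at least 2-fold higher and 1271 lower than with the empty vector, and 855 and 845 passed 2-fold against both controls.

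Fat cell genes moved as a group. Of 20 measured fat cell markers, 18 were at least 2-fold higher and 0 lower, with a median log2 difference of 4.73. PPARg target genes (14 of 16, median 5.49), lipid droplet genes (12 of 17, median 2.77) and lipid synthesis genes (14 of 19, median 1.94) were higher as well. Droplet genes included the lipases Pnpla2 (4.63) and Mgll (4.55), with Plin3 going the other way (-1.26). Among lipid synthesis genes the triglyceride enzymes Dgat2 (4.76), Agpat2 (3.72), Dgat1 (3.58) and the carboxylase Pcx (3.32) were highest, and the elongase Elovl6 was lower (-1.91). Adipokines had 3 of 6 measured members higher (Adipoq, Retn at 4.71 and Agt at 3.70; median 2.13). That median rests on the level filter, since without it the list had 0.524, and 0.233 and 0.064 in the A- and M-fraction. Adipogenic transcription factors had 6 of 14 higher and 0 lower (median 0.83), with the liver X receptor gene Nr1h3 at 3.43, Cebpa at 3.20, Srebf1 at 2.23 and Egr2 also above 2-fold. Against non-infected cells PPARg target genes had a median of 4.80 and lipid synthesis one of 1.59. Of 10000 random lists, 0 had a median as high for the first 5 groups and 4 for the transcription factors. Thermogenic fat genes had 5 of 9 members higher (median 1.01), with Cox8b at 4.55, Elovl3 at 3.04 and Otop1 at 1.38, and Tbx1 lower (-1.88). Without the filter this median was 0.588.

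Mitochondrial and sterol genes were higher with PPARg too. Fatty acid oxidation had 17 of 20 members at least 2-fold higher (median 1.79), led by the peroxisomal enzyme Ehhadh (4.59), Etfdh (2.72), Decr1 (2.67) and Acadvl (2.65). The respiratory chain had 22 of 31 higher (median 1.46), with Uqcrfs1 at 2.19, Ndufs1 and Cyc1 at 2.06 and Ndufb3 at 2.02. Sterol synthesis had 16 of 17 higher (median 2.13), among them Dhcr7 (3.21), Lss (3.06), Idi1 (3.05) and the sterol sensor gene Insig1 (2.94). For each of the 3 lists, 0 of 10000 random lists had a median as high. Against non-infected cells the respiratory chain median was 1.12, and that of sterol synthesis 0.40 with 5 of 17 genes 2-fold higher, so most of the sterol difference rested on the empty-vector array. Glycolysis had a median of 0.56, with Pfkl (2.14), Hk2 (1.81), Aldoa (1.43) and Pdk1 (1.13) 2-fold higher and the glucose transporter Slc2a1 lower (-1.11), and a median of -0.05 against non-infected cells.

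Matrix, contractile and signalling genes of fibroblasts were lower with PPARg. Fibroblast matrix had 17 of 26 members at least 2-fold lower (median -1.80), among them Dcn (-4.26), the collagen cross-linking enzyme Lox (-3.62), Fbln2 (-3.11) and the growth factor receptor Pdgfra (-3.11), and 1 higher, Col6a3 (1.67). Dcn, at log2 6.86 with PPARg, was less than 2-fold below non-infected cells. Smooth muscle and stress fibre genes had 6 of 13 lower (median -0.55), including smooth muscle actin Acta2 (-4.14), Cald1 (-2.73), Synpo2 (-2.35) and Smtn (-1.97), with desmin, Des, higher (1.85). Inflammation had 8 of 17 lower and 0 higher (median -0.98), with the chemokine Cxcl5 (-4.12), Csf1 (-3.42), Vcam1 (-3.17) and Ptgs2 (-3.15), and TGF-beta had 8 of 18 lower (median -0.94), with Tgfbi (-2.97), Tgfb3 (-2.55), Ltbp2 (-2.37) and Tgfb2 (-1.61). Bone genes had 4 of 8 lower (median -1.27): Bmp4 (-4.36), Dlx5 (-3.16), Col1a1 (-2.88) and Phex (-2.18). Against non-infected cells the bone median was -0.28, that of inflammation -0.58 and that of smooth muscle -0.89. Without the filter the bone median was -0.149. Wnt genes had 6 of 20 lower with a median of -0.01, and 3 lower and 1 higher against non-infected cells (median 0.09). Cell cycle genes had a median of -0.46 against the empty vector and of -1.68 against non-infected cells of unknown density, where 32 of 39 were 2-fold lower.

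Medians of the muscle lists stayed near the empty vector with PPARg alone, with members going both ways. Sarcomere genes had a median of 0.15, with 1 of 44 higher (Myl1, 1.86) and 5 lower, the tropomyosins Tpm1 (-3.46), Tpm2 (-2.15) and Tpm3 (-1.11), Actn3 (-1.11) and Tnni1 (-1.11). Myogenic regulators had a median of 0.09, with 3 of 21 higher and 3 lower, Eya4 at -2.33, Mef2c at -1.50 and Id3 at -1.17. Medians were -0.03 for myoblast fusion, where 5 of 16 were lower and 2 higher, 0.15 for the acetylcholine receptor and synapse, 0.15 for calcium handling and 0.22 for muscle energy metabolism. Within these, Myof (-3.44), Ncam1 (-3.22), Lrp4 (-1.68) and Cacna2d1 (-2.83) were lower, and Itga7 (2.36) and Adam12 (2.17) higher. Interferon genes had a median of -0.08, with Usp18 4.6-fold higher and Ifit3 (-2.61), Ifit1 (-2.22) and Ddx58 (-1.69) lower. Against non-infected cells Ifit1 (0.895) and Ifit3 (0.048) were not lower, and the list median was 0.19.

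Lists of other cell types and pathways showed small medians with PPARg. They were 0.02 for cartilage, where Sox9 alone was 2-fold lower (-2.90), 0.08 for macrophages, 0.09 for endothelium, 0.06 for neurons, 0.09 for epithelium, 0.24 for Notch, 0.20 for p53, 0.32 for the unfolded protein response (-0.05 against non-infected cells) and -0.23 for ribosomal proteins. Endothelial Eng (-2.19) and Tek (-1.33), neuronal Stmn2 (-3.48) and Map2 (-2.59), and Notch3 (-1.36) were lower, and Dnajb9 (2.27) and Asns (1.79) of the unfolded protein response were higher. In the fractions against the empty vector, the medians of these 9 lists lay between -0.24 and 0.46. Sox9 was at -2.44 in the A-fraction and -2.32 in the M-fraction, and of the macrophage and epithelial markers 0 were 2-fold apart in either fraction.

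**Figure D2:**
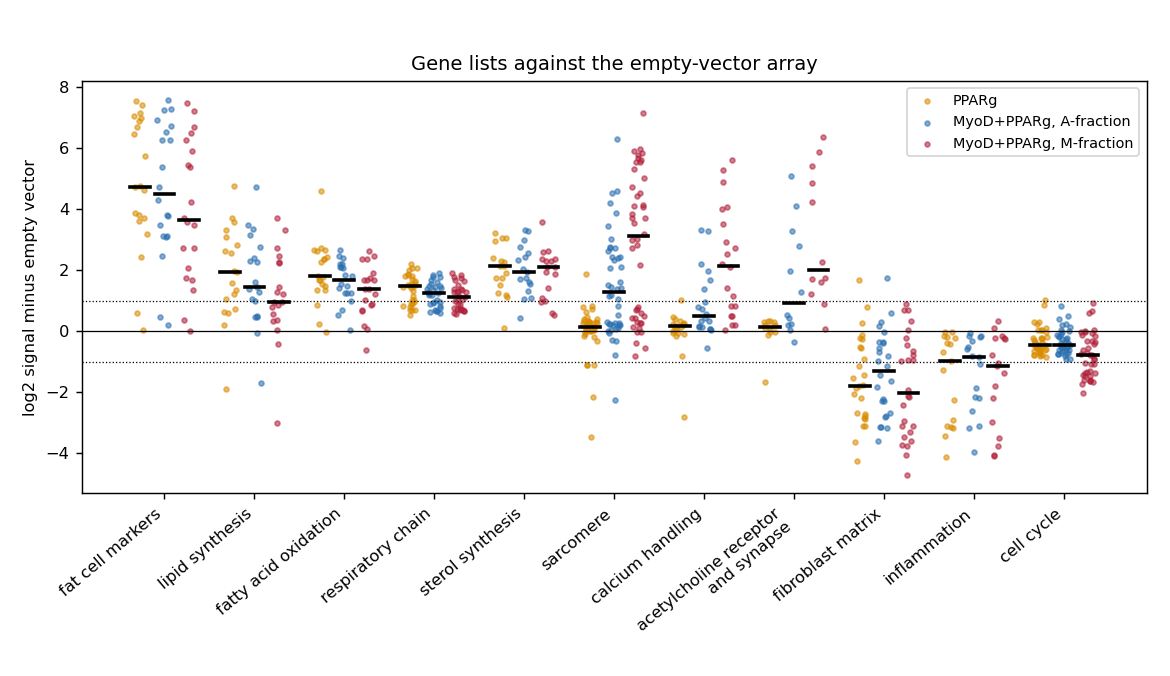
Log2 signal minus the empty-vector array (vertical axis) for each measured member of 11 gene lists, with 1 point per gene and a bar at the median; orange is PPARg alone, blue the A-fraction and red the M-fraction. Fat cell markers had medians of 4.73, 4.51 and 3.64 and sarcomere genes of 0.15, 1.29 and 3.11 in that order, and dotted lines mark 2-fold.

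The A-fraction was compared with the empty vector to see which programme its cells carried. Car3 was 192-fold, Adipoq 157-fold, Cd36 152-fold and Fabp4 122-fold higher, followed by Aqp7 (106-fold), Lpl (92.7-fold) and Gpd1 (77.6-fold). Among these fat cell genes stood the muscle myosin light chain Myl1, at 79.4-fold. The lowest genes were Sfrp2 (-5.54), Ccn3 (-4.63), C1s1 (-4.45), the aminopeptidase Anpep (-4.45), P4ha3 (-4.38), Sfrp1 (-4.34), Adamtsl3 (-4.17) and Dpysl3 (-4.05). Against non-infected cells 5 of these lay much closer, Sfrp2 at -2.53, Ccn3 at -2.34, C1s1 at -1.37, Anpep at -2.85 and Sfrp1 at -1.41. In all, 1023 genes were at least 2-fold higher and 1047 lower, and 772 and 649 passed against both controls.

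Fat and muscle genes were both higher in the A-fraction. Fat cell markers had 18 of 20 at least 2-fold higher (median 4.51), PPARg target genes 14 of 16 (5.22), lipid droplets 12 of 17 (2.56), lipid synthesis 13 of 19 (1.45), adipokines 3 of 6 (1.97), adipogenic transcription factors 6 of 14 (0.49) and thermogenic fat 4 of 9 (0.62). Elovl6 (-1.71), Plin3 (-1.20) and Tbx1 (-1.89) went against their lists. The highest thermogenic genes were Cox8b, also on the muscle energy list, and Fabp3 (2.81), both more than 2-fold above PPARg alone. Against non-infected cells PPARg target genes had a median of 4.32, lipid synthesis one of 1.07 and the transcription factors one of 1.07. Fatty acid oxidation had 16 of 20 higher (median 1.69), sterol synthesis 16 of 17 (1.93) and the respiratory chain 20 of 31 (1.25). The last 2 medians were 0.51 and 0.99 against non-infected cells. Sarcomere genes had 25 of 44 at least 2-fold higher (median 1.29), with the troponins Tnnc1 (4.59), Tnnt2 (4.53) and Tnnt3 (4.19) after Myl1, and Tpm1 alone lower (-2.25). The myogenic regulator list had 7 of 21 members higher (median 0.48), led by Chrna1 (5.10), Myog (4.45), Rb1 (2.25) and Des (2.21), with Eya4 lower (-1.50). The acetylcholine receptor and synapse had 6 of 12 higher (median 0.92), calcium handling 6 of 20 (0.51) and muscle energy metabolism 7 of 16 (0.53). Their highest members were the receptor subunits Chrng (4.12) and Chrnd (3.29), the calcium pump Atp2a1 (3.30), and Cox8b (6.10) and the muscle enolase Eno3 (2.30), with Ppp1r3c lower (-1.11). Rb1 (1.80), Des (1.85) and Cox8b (4.55) were already above 2-fold with PPARg alone. The myoblast fusion list had a median of 0.07, with Mymk, which encodes the fusion protein myomaker, at 5.08 and Itga7 at 3.73, but Myof at -2.16, Kirrel at -1.69, Jam2 at -1.23 and Jam3 at -1.03.

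Genes of the fibroblast state were lower in the A-fraction. Fibroblast matrix had 14 of 26 at least 2-fold lower (median -1.30), with Dcn at -3.60, Pdgfra at -3.19 and Fbln2 at -3.14, and Col6a3 again higher (1.76). Medians were -0.53 for smooth muscle, -0.85 for inflammation, -1.29 for bone, -0.43 for TGF-beta, -0.02 for Wnt, -0.46 for the cell cycle, -0.32 for interferon and 0.37 for glycolysis. Against non-infected cells the medians were -1.73 for the cell cycle, -0.22 for bone, -0.42 for inflammation, -0.23 for TGF-beta, -0.07 for interferon and 0.12 for glycolysis. Without the filter the bone median was -0.159.

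The M-fraction was compared with the empty vector in the same way. Fat and muscle genes stood side by side among its highest genes: Car3 (178-fold), Cd36 (150.3-fold), Myl1 (143-fold), Fabp4 (103-fold), Adipoq (91.0-fold), the acetylcholine receptor subunit Chrna1 (82.2-fold), the membrane protein gene Tmem182 (78.1-fold) and Aqp7 (77.6-fold). The lowest were Sfrp2 (-6.03), Ccn3 (-5.87), the matrix proteoglycan Vcan (-5.49), C1s1 (-5.11), P4ha3 (-5.04), Anpep (-5.03), the morphogen Bmp4 (-4.74) and Dcn (-4.71). Against non-infected cells Sfrp2 was at -3.01, Ccn3 at -3.58, Vcan at -4.53, C1s1 at -2.02, Anpep at -3.43 and Dcn at -1.42. In all, 1076 genes were at least 2-fold higher and 1401 lower, and 817 and 919 passed against both controls.

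Medians of the sarcomere, synapse, calcium handling, muscle energy and myogenic regulator lists were higher here than with PPARg alone or in the A-fraction. Sarcomere genes had 27 of 44 at least 2-fold higher and 0 lower (median 3.11), with Myh3 at 5.99, Tnnc1 at 5.91 and titin, Ttn, at 5.85. The acetylcholine receptor and synapse had 10 of 12 higher (median 2.01), with Chrng (5.87), Chrnd (5.41) and Chrnb1 (4.85), and calcium handling 13 of 20 (2.14), with Atp2a1 (5.62), Srl (5.29), the calcium release channel Ryr1 (4.89) and Casq2 (4.08). Muscle energy metabolism had 8 of 16 higher (median 1.31), with Eno3 (3.99), Pgam2 (3.97) and myoglobin, Mb (3.57), and 1 lower, Ppp1r3c (-1.24). The myogenic regulator list had 10 of 21 members higher (median 0.89), with Myog (5.95), Ankrd2 (3.51) and Des (3.40). The fusion list had 7 of 16 higher and 1, Kirrel (-1.13), lower, with a median of 0.07, and Mymk (5.98), Itga7 (4.996), Mymx (3.36) and Cdh15 (2.72) were highest. The Notch ligand gene Dll1 was at 3.39 and Notch3 at -1.40 while the Notch median was 0.12.

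Fat cell genes were high in the M-fraction as well. Fat cell markers had 18 of 20 at least 2-fold higher (median 3.64), PPARg target genes 14 of 16 (4.18), lipid droplets 11 of 17 (1.42), lipid synthesis 9 of 19 (0.96), adipokines 3 of 6 (1.35), adipogenic transcription factors 4 of 14 (0.18) and thermogenic fat 2 of 9 (0.43). Fatty acid oxidation had 13 of 20 higher (median 1.37), the respiratory chain 18 of 31 (1.10) and sterol synthesis 13 of 17 (2.09). Against non-infected cells the sterol median was 0.55, that of PPARg target genes 3.70 and that of lipid droplets 1.92. Elovl6 (-3.00), Ebf1 (-1.98), Plin3 (-1.65), Cideb (-1.19) and Tbx1 (-2.55) went against their lists. Fibroblast matrix had 14 of 26 lower and 0 higher (median -2.03), with Pdgfra at -4.08, Fbln2 at -3.78 and Pdgfrb at -3.75, and inflammation had 10 of 17 lower (median -1.16). The median was -1.76 for bone, -0.24 for smooth muscle, -0.14 for TGF-beta, -0.11 for Wnt, -0.62 for interferon and 0.55 for glycolysis. Against non-infected cells inflammation was at -0.64, bone at -0.52, TGF-beta at -0.26, interferon at -0.11 and glycolysis at -0.08, so that glycolysis turned. Without the filter bone was at -0.135, inflammation at -0.274 and muscle energy metabolism at 0.783. Cell cycle genes had 17 of 39 at least 2-fold lower (median -0.79), with Ccna2 at -2.04, Top2a at -1.73 and Mki67, the gene of the Ki-67 proliferation antigen, at -1.67, and a median of -2.07 against non-infected cells.

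The calls of PPARg alone and of the A-fraction overlapped widely. Of the genes at least 2-fold higher with PPARg, 826 of 1110 were also higher in the A-fraction, and of those lower, 974 of 1271 were lower there. Independent lists of these sizes would share 76.5 and 89.6 genes, and simulated unchanged arrays sharing a control shared a median of 86 and 119 and at most 115 and 155. Part of the excess may come from the shared control. With the non-infected array as the control of the PPARg array, 701 and 697 genes were shared. The PPARg array and the M-fraction shared 522 higher and 923 lower genes (449 and 706 with separate controls), where independent lists would share 80.4 and 119.9. The fractions shared 658 higher and 897 lower genes (546 and 658 with separate controls), where independent lists would share 74.1 and 98.8.

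The fractions were compared with each other. Whether both came from 1 co-infected culture is not given in the sources used here, so cell size and culture cannot be separated. Muscle genes were lower in the A-fraction: Myh3 by 9.4-fold, Myh1 and the thin filament gene Neb by 7.9-fold, Itgb1bp2 by 7.0-fold, Xirp1 and Tm6sf1 by 6.5-fold, and Casq2 and Ryr1 by 6.4-fold. The genes highest in the A-fraction differed less. They were the fat cell gene Adig (3.8-fold), the matrix genes Efemp1 (3.7-fold), Postn (3.2-fold) and Vcan (3.2-fold), Ramp2 (3.4-fold), the alcohol dehydrogenase Adh1 (3.3-fold), St3gal6 (3.2-fold) and Ptn (3.2-fold). In all, 346 genes were at least 2-fold higher and 407 lower in the A-fraction, and 12 and 172 at 3-fold.

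Sarcomere genes had 26 of 44 at least 2-fold lower in the A-fraction and 0 higher (median -1.51). Medians were -1.53 for calcium handling (13 of 20 lower), -1.39 for the acetylcholine receptor and synapse (8 of 12), -0.76 for muscle energy metabolism (7 of 16), -0.78 for fusion (7 of 16) and -0.66 for myogenic regulators (7 of 21). Mef2c (-2.17) and Cdh15 (-1.71) differed most in the myogenic regulator list, and Pgam2 (-2.61), Casq1 (-2.36), Ache (-2.24) and Ncam1 (-2.19) were among the lowest of theirs. For each of these 6 lists, 0 of 10000 random lists had a median as low. Fat cell markers were higher in the A-fraction, 7 of 20 by at least 2-fold and 0 lower (median 0.80), with Pck1 (1.44), Cebpa (1.34), Plin1 (1.17) and Plin4 (1.12), whereas Cd36 (0.02) and Fabp4 (0.25) were nearly equal. Lipid droplet (median 0.60), lipid synthesis (0.65), PPARg target (0.69), adipokine (0.80), adipogenic transcription factor (0.57) and fibroblast matrix lists (0.58) were also higher, the matrix list with Thbs1 (-1.68) and Ccn1 (-1.25) against it. Cell cycle genes had a median of 0.43, with Cdk1 (1.44), Mki67 (1.13), Ccna2 (1.12) and Top2a (1.12) higher and Rrm1 lower (-1.05). The respiratory chain (0.08) and sterol synthesis (0.11) were alike in both fractions, and fatty acid oxidation had a median of 0.34 with 0 of 20 members 2-fold apart.

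**Figure D3:**
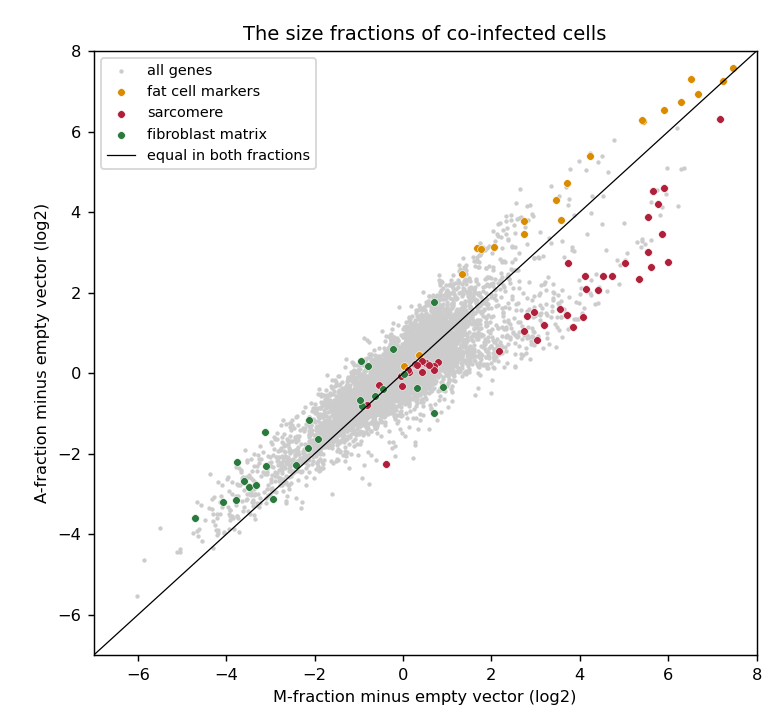
Log2 difference from the empty vector in the M-fraction (horizontal axis) and the A-fraction (vertical axis), with 1 point per gene and the line of equal values. Sarcomere genes (red, medians 3.11 and 1.29) lie below the line, fat cell markers (orange, 3.64 and 4.51) on or above it, and most fibroblast matrix genes (green) lie low in both.

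The A-fraction was compared with PPARg alone. These arrays differ by the MyoD virus, by the separation on size and by any carried-over myotubes, so the differences cannot be ascribed to MyoD alone. All of the 8 genes furthest above PPARg alone belong to muscle or are high in muscle cultures: Mymk (28.9-fold), Chrna1 (27.8-fold), the troponins Tnnc1 (25.7-fold), Tnnt2 (18.9-fold) and Tnnt3 (17.9-fold), Myl1 (21.9-fold), Myog (18.1-fold) and the growth factor gene Igf2 (17.4-fold). The genes furthest below were the carboxylesterases Ces1d (-2.50) and Ces1f (-2.34), the chemokine Ccl9 (-2.45), the prolactin family member Prl2c5 (-2.38), the metalloreductase Steap4 (-2.15), Glyat (-2.10), the fatty acid elongase Elovl3 (-1.95) and Ehhadh (-1.95). In all, 232 genes were at least 2-fold higher and 41 lower, and 98 and 11 at 3-fold. Of the 232 genes, 190 were higher still in the M-fraction. Of the 41 lower genes, 37 were lower still in the M-fraction, as were 902 of the 1110 genes higher with PPARg than with the empty vector. With PPARg 35 of the 41 were at least 2-fold above the empty vector, a count that shares the PPARg array with the choice of these genes. The 232 and the 41 are fewer than the 313 and 315 between the controls, which also differ by the virus and are not replicates.

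Fat cell markers differed little between these arrays, with 0 of 20 at least 2-fold apart and a median of -0.23. The largest differences were in Retn (-0.94), Pck1 (-0.70), Slc2a4 (-0.49) and Gpd1 (-0.41). Of 10000 random lists 6 had a median as low. Medians were -0.26 for fatty acid oxidation, where Ehhadh alone was 2-fold lower, -0.20 for lipid droplets, -0.18 for lipid synthesis, -0.15 for the respiratory chain and 0.01 for sterol synthesis. Sarcomere genes had 22 of 44 at least 2-fold higher and 0 lower (median 0.95), which became 1.94 with the stricter level filter. The acetylcholine receptor and synapse had 7 of 12 higher (median 1.21), calcium handling 9 of 20 (0.84), fusion 5 of 16 (0.64), myogenic regulators 5 of 21 (0.44) and muscle energy metabolism 4 of 16 (0.32). Acta2, 3.49 higher on the log2 scale, stood out in the smooth muscle list (median 0.11). Interferon genes had 2 of 21 lower (median -0.30), Ifit1 (-1.33) and Usp18 (-1.25). TGF-beta genes had 3 of 18 higher (median 0.39), Tgfb3 (1.54), Pmepa1 (1.53) and Id2 (1.18).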

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

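The tests of the 41 genes below PPARg alone, with the simulated mixtures, were chosen after that result was seen. Some genes lay at least 2-fold on opposite sides of the empty vector in different arrays, which was not tested for lack of replicates. With PPARg alone lower and the M-fraction higher there were 24 genes, among them Runx1 (-2.16 and 2.96), Ncam1 (-3.22 and 2.01), Cryab (-2.97 and 2.14), Tpm2 (-2.15 and 2.81) and Mef2c (-1.50 and 1.63), and with PPARg higher and the M-fraction lower 1, Prl2c5 (1.11 and -1.85). In the A-fraction 6 genes were higher and with PPARg lower (Actn3, Mustn1, Runx1, Slc29a1, Tnni1 and Tpm2), and 1 the reverse, Prl2c5 (-1.28 in the A-fraction). Against non-infected cells the PPARg side of Tnni1 (0.23) and of Prl2c5 (-0.41) turned, so that Prl2c5 lay below that control in all 3 arrays, and Mef2c was at -0.88. Cand2 (-0.68), Porcn (-0.35) and Ralgps2 (-0.35) with PPARg, Fyn in the M-fraction (0.88) and Slc29a1 in the A-fraction (0.99) also fell short of 2-fold there. The counts of 24 and 6 therefore depend on the control. Of 3726 probe sets past the filter without a single gene symbol, which the comparisons left out, 94 were at least 2-fold above both controls with PPARg alone, 80 in the A-fraction and 101 in the M-fraction.

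Muscle genes were high in the adipocyte-enriched A-fraction. A candidate explanation is carry-over of myotubes or their RNA, since separation by size enriches and does not purify. Carry-over into cells at the empty-vector level gives every muscle gene a like share of its signal above that level in the M-fraction. PPARg alone already raised Rb1 (1.80) and Des (1.85) of the myogenic regulator list and Myl1 (1.86) of the sarcomere list above it. The shares of such genes can therefore also hold an effect of PPARg. The median share was 0.180 for 27 sarcomere genes (Xirp1 at 0.090 to Myl1 at 0.550) and 0.343 for 7 genes of the myogenic regulator list. The log2 difference was -0.931 (95% interval -1.37 to -0.02 over genes), which lies between the bounds set beforehand. The regulator list also holds Chrna1 and Des, so this was no clean contrast of regulators with structural genes. Median shares were 0.250 for 6 acetylcholine receptor and synapse genes, 0.163 for 11 calcium handling genes and 0.162 for 7 muscle energy genes. By the planned test, carry-over and muscle gene activity in the A-fraction's own cells cannot be told apart. The latter is a biological explanation that the design allows. The range of single shares does not decide it, since a share of 1 gene has no replicate spread.

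Fat cell genes were high in the myotube-enriched M-fraction. Carry-over of fat cells is again a candidate explanation. Another is PPARg acting in myotubes, since the cells were given its virus too. Pparg was 3.95 times the empty vector in the M-fraction and 4.66 times in the A-fraction. That signal is of the whole fraction, so whether the myotubes themselves carried the virus was not measured. The median share of the A-fraction's signal was 56.3% for 13 PPARg target genes (Pck1 at 28.7% to Cd36 at 98.9%) and 45.0% for 3 adipokines, a log2 difference of 0.323 (-0.11 to 0.73). With 3 adipokines, of which Adipoq is in both lists, this test has little power, and the explanations cannot be told apart. Cd36, Fabp4 and Plin2 had shares of 98.9%, 83.7% and 95.7%, and Plin1 and Plin4 of 43.2% and 34.0%. Cd36 is also expressed in muscle.

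The A-fraction lay at least 2-fold below PPARg alone in 41 genes, fewer than the 315 between the controls, so a difference between separate cultures is not excluded as their cause. The controls also differ by the virus, so their count is not a replicate spread. By the same measure the 232 higher genes were fewer than the 313 between the controls, but a count says nothing of which genes differ. Of 44 sarcomere genes 22 were at least 2-fold higher in the A-fraction than with PPARg alone, and 1 was between the controls. A 2-fold smaller share of fat cells is argued against, because it lowers fat genes alike, and the 18 fat cell markers had a median log2 share of -0.265 (-0.36 to -0.10), above the -1 that this needs. This bound was set after the results were seen. Single markers ran from 50.1% (Retn) to 111.7% (Car3) with a median of 83.2%, so a slightly smaller share is not excluded as part of the difference. The 0.000 (-0.25 to 0.84) between PPARg target genes and adipokines decides nothing, since Adipoq, with a share of 83.8%, is the median of both lists. For mixing with M-fraction-like cells, the mixing share was 0.185 for 271 genes at least 4-fold higher in the M-fraction and 0.651 for 39 lower ones, a difference of 0.466 (0.39 to 0.52). In 1000 simulations each, exact mixtures gave 0.691 (0.632 to 0.736) with 309 genes 2-fold lower where the PPARg culture differed as the controls do. They gave 0.403 (0.245 to 0.568) with 43 at 0.5 of that difference and 0.088 (-0.022 to 0.298) with 0 at 0.25 of it. Genes at least 4-fold lower in the M-fraction numbered 92, 14 and 4 in these settings, against 39 in the data. No setting tried thus came near both the 41 and the 39. The data passed the bound that was set for the difference in mixing share after the results were seen. Exact mixtures passed it too, at the full difference between the controls and at 0.5 of it, so passing it decides nothing. The outcome depends on a culture difference that was not measured, and mixing cannot be told apart from the rest. An effect of MyoD on these genes, virus dose and maturity of the fat cells stay open and were not tested.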

How the results depend on the processing

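All alternatives were planned. Apart from the 3-fold threshold, the 66 recomputed counts of genes stayed within 1.5 times the reported ones, as did the overlap of PPARg and A-fraction calls (1398 to 1802 against 1800). At 3-fold the counts higher and lower were 105 and 68 for the control pair, 519 and 640 for PPARg, 468 and 483 for the A-fraction and 547 and 655 for the M-fraction against the empty vector, 12 and 172 for the A-fraction against the M-fraction, and 98 and 11 against PPARg, and the overlap was 816, since a stricter threshold calls fewer genes. After either rescaling the median differences of all genes lay between -0.048 and 0.063, and no named gene turned. The stricter filter, which drops dim members, moved the fat cell marker median to 5.257 (PPARg), 5.055 (A-fraction) and 3.966 (M-fraction), and that of sarcomere genes to 1.833 and 3.963 in the A- and M-fraction, -1.780 between the fractions and 1.941 for the A-fraction against PPARg. Without a filter the fat cell marker median of the A-fraction was 4.052, and lists with many dim members lost most of theirs, such as adipokines (0.524, 0.233 and 0.064 with PPARg, in the A-fraction and in the M-fraction, from 2.131, 1.973 and 1.352), bone (-0.149, -0.159 and -0.135, from -1.269, -1.294 and -1.756) and inflammation in the M-fraction (-0.274, from -1.158). Thermogenic fat with PPARg (0.588) and muscle energy metabolism in the M-fraction (0.783) also lay lower. Over all lists, 999 of 1098 recomputed medians moved little and 99 moved, 39 of them with the non-infected array as the control. That control put Pparg at 3.071 (PPARg), 2.977 (A-fraction) and 2.739 (M-fraction) and turned 10 single values among the genes that the naming rule gives. With PPARg these were Ccne2 (-0.214), Ifit1 (0.895), Ifit3 (0.048), Phex (0.565) and Tnni1 (0.231), in the A-fraction Chac1 (-0.535), Phex (0.382) and Ppp1r3c (0.132), and in the M-fraction Chac1 (-0.088) and Ppp1r3c (0.007). Prl2c5 with PPARg, named outside that rule there, turned as well (-0.41). The gap between the 2 controls in these genes sets this, and why the controls differ was not tested. No paired analysis was possible because each group has 1 array. Signals under the filter level of 57.57 are near background, so folds against them depend on that level.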

Other observations

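Most genes in these 2 paragraphs were chosen after their values were seen, no tests were made on them, and no explanation is offered. Several genes of amino acid and one-carbon metabolism were lower with the empty vector than in non-infected cells. Psat1 of serine synthesis was at log2 11.01 in non-infected cells, 8.70 with the empty vector, 10.29 with PPARg, 10.41 in the A-fraction and 11.25 in the M-fraction. The mitochondrial folate enzyme Mthfd2 (9.45, 7.36, 8.99, 9.57 and 10.55 in the same order), asparagine synthetase Asns (11.20, 9.54, 11.32, 11.42 and 11.76), the glutathione-degrading enzyme Chac1 (9.09, 6.85, 7.84, 8.55 and 8.999) and the amino acid transporter Slc7a5, which was 2.95 higher on the log2 scale in the M-fraction than with the empty vector, had the same low point in the empty-vector array. The cystine transporter Slc7a11 (8.32, 5.97, 6.11, 6.50 and 6.04) and Aldh1l2 (9.38, 7.07, 6.69, 6.93 and 8.12) did not return to the non-infected level in the other arrays.

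Interferon-linked genes went separate ways with PPARg. Usp18 (6.30, 7.84, 10.05, 8.80 and 7.56 in the order non-infected, empty vector, PPARg, A-fraction, M-fraction) and Ifi27l2a (5.96, 6.27, 9.80, 8.59 and 7.10) were highest with PPARg alone, whereas Ifit1 (6.45, 9.56, 7.35, 6.02 and 5.64) and Ifit3 (6.99, 9.65, 7.03, 6.26 and 5.74) were highest with the empty vector, and Bst2 lay between 7.03 and 7.33 in every array. Ndrg2, a gene expressed in both fat and muscle, was at 7.55 with PPARg, 9.96 in the M-fraction and 11.27 in the A-fraction. Igf2 was at 7.39 with PPARg, 11.51 in the A-fraction and 12.30 in the M-fraction, and Tmem182 at 10.88, 11.26 and 12.49, so that the signal of Tmem182 with PPARg alone was already far above the 6.20 of the empty vector.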
